A study of Mus musculus with 20 samples.

How the data were processed

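RNA sequencing measured gene expression in 18 mouse osteosarcomas and in 2 libraries of 1 osteosarcoma cell line. Per the labels, RNA was isolated with Trizol and column kits and total RNA was sequenced with Illumina protocols. The authors checked the reads with FastQC, aligned them to GRCm38 with STAR 2.6.0b and compared groups with DESeq2, whose version is not given. The deposited table holds raw counts, with 1 column per library and 49585 mouse gene IDs, of which 49326 matched a gene symbol in a reference table. The program that counted the reads, its annotation, its strand setting and the sequencing batches are not given. All 20 columns were used, and no normalized table of the authors was used here.

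Groups follow the labels: p53+/- (n = 4), p53R172H/+ (n = 6), p53R245W/+ (n = 3) and p53R270H/+ tumours (n = 5), and control and p53 siRNA of cell line 14 (1 library each). No paired analysis was possible because replicate numbers follow accession order. Total counts ran from 20.1 to 29.2 M (megacounts) per tumour library and were 64.1 and 73.4 M in the line. The floor, 3 counts over the library total, was 0.103 to 0.149 CPM in the tumours. Intervals are exact Poisson intervals at a confidence level of 95%.

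Tumour counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passed filterByExpr with the genotype as group (minimum count 10, minimum total count 15), which left 20616 genes. Libraries were scaled by TMM, and 1 quasi-likelihood model with a mean per genotype (14 residual degrees of freedom) gave 6 contrasts and a test for any difference. p-values measure the spread between tumours of a genotype and were adjusted by Benjamini-Hochberg within each contrast with a threshold of 0.05. The standard error of a log2 fold is its size divided by the square root of the F statistic, and log2 CPM used a prior count of 2. Trp53 was also compared by exact two-sided permutation of log2 CPM, adjusted over the 6 contrasts.

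Named genes were chosen by a fixed rule. For a mutant against p53 het these were the 8 highest and 8 lowest log2 folds among genes that passed, had a mean of at least 1 CPM and did not overlap between groups, and for 2 mutants 5 a side. Where fewer than 5 genes met this, the lowest p-values filled the number, and where fewer than 5 passed, the 5 lowest are given as not passed. Genes known only by a model number, pseudogenes with that name ending and antigen receptor segments were passed over. Trp53, Cdkn1a and Mdm2 are given for every group, and lists are described by their members of lowest p, apart from some members that are not reported here.

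A set of 37 gene lists was tested with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over 222 tests of list and contrast. The pathway lists were p53 target genes, mitosis, DNA replication, homologous recombination, reported mutant p53 gain-of-function targets, mevalonate and cholesterol synthesis, proteasome, hypoxia and glycolysis, oxidative phosphorylation, MYC and ribosome biogenesis, unfolded protein response, TGF-beta response, epithelial-mesenchymal transition and invasion, Wnt targets and feedback genes, Notch, interferon response, antigen presentation, inflammatory cytokines and NF-kB, and posterior Hox genes. The cell type lists were osteoblast and osteocyte, chondrocyte, osteoclast, fibroblast, skeletal muscle, macrophage, T and NK cell, B and plasma cell, neutrophil and granulocyte, erythroid, endothelial, adipocyte, epidermis, Schwann cell and lung epithelium. Immediate early genes, mitochondrially encoded genes and non-polyadenylated RNA served as technical lists. The groups, contrasts, naming rule and first group of settings were set before the data were examined.

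The cell line has no replicate, so no test was made. Ratios are log2 of CPM plus 1, named genes needed 10 CPM in 1 library, and list medians were set against 10000 random lists of the same size and like expression. Contrasts that share p53 het were set against 20 simulated sets with no difference. With simulated changes of 2-fold, 4-fold and 8-fold in 67, 67 and 66 genes, edgeR recovered 10.4%, 58.2% and 72.7% for R172H against p53 het, and 22.4%, 68.7% and 83.3% for R270H against R172H. In the latter DESeq2 1.42.0 recovered 29.9%, 86.6% and 89.4%, with 32 false among 169 calls, where edgeR had 3 among 119 and limma voom 7 among 119.

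Other settings tried were DESeq2, its size factors in edgeR, no low-count filter, limma voom with sample quality weights, a fit of only the groups compared, p53 het without libraries 3 and 4, a skeletal muscle score, Xist or 1 surrogate variable (sva 3.50.0) as a covariate, leaving out each library, camera with an estimated correlation, and fry. For the line they were CPM plus 0.1 or 5, TMM, a minimum of 1 CPM, and other gene sets. Settings added after the data were seen were the kind of title (with or without a serial number) as a covariate, only p53 het 3 and 4 for R270H, removal of each library's trend with GC content, and protein-coding genes only. Group labels were also redrawn in at most 100 splits per contrast. Splicing, variants and reads outside genes were not analysed here.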

Results

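Bulk RNA sequencing of total RNA measured gene expression in 18 primary osteosarcomas, malignant bone tumours, of mice on a mixed C57BL/6J and 129S/SvJae background, and in a cell line grown from such a tumour. Of the tumours, 4 came from p53+/- mice, which carry a lost allele of Trp53 (here p53 het). The others came from mice with a missense allele in place of the lost one: 6 from p53R172H/+, 3 from p53R245W/+ and 5 from p53R270H/+ mice (here R172H, R245W and R270H). The comparisons address which genes differ between tumours with a mutant p53 protein and tumours with a lost allele, and whether the 3 mutants differ from each other. The labels do not say whether a tumour kept its wild-type allele, nor do they give the sex of the mice or the site of the tumour. Total counts, in M (megacounts), ran from 22.8 to 29.2 M per library in p53 het and from 20.1 to 28.8 M in R172H tumours. They ran from 22 to 24 M in R245W and from 20.7 to 26.8 M in R270H tumours. A count of 3, taken as the limit that a count of 0 allows, equals 0.103 to 0.149 CPM, counts per M counts of the library, in these libraries. The label of cell line 14 gives p53R245/O, and of its control a heterozygous mutant with loss of heterozygosity; that the mutant is R245W is inferred here, as the labels name no other change of this codon. Its 2 libraries held 64.1 M (control) and 73.4 M counts (siRNA against p53). Intervals and floors cover counting error only.

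Every tumour library had Xist reads, and the sum of 4 Y-linked genes was at most 0.746 CPM. Xist, the RNA that silences an X chromosome, lay between 631 and 1749 CPM in 17 tumours and at 148 CPM in R172H 2. The first 3 principal components held 15.1%, 12.5% and 10.9% of the variance. The second placed the 5 R270H libraries (32.7 to 63.8) with p53 het 3 (51.1) and, more weakly, p53 het 4 (6.58), above all other tumours. The titles divide the libraries in the same way. Those of p53 het 1 and 2 and of all R172H and R245W tumours carry a serial number. Those of p53 het 3 and 4 and of all R270H tumours do not. The R270H titles also share a code of their own that no other title holds. The titles of p53 het 3 and 4 thus have only the lack of a serial number in common with them. A batch that follows the R270H code alone cannot be told from the R270H genotype. Results are therefore given also within a title code: against p53 het 1 and 2 alone for R172H and R245W, and with the code as a covariate for R270H. That covariate is estimated only from p53 het 1 and 2 against 3 and 4, since each mutant group holds 1 kind of title. In this text ± is the standard error for log2 folds and the standard deviation for CPM.

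**Figure D1:**
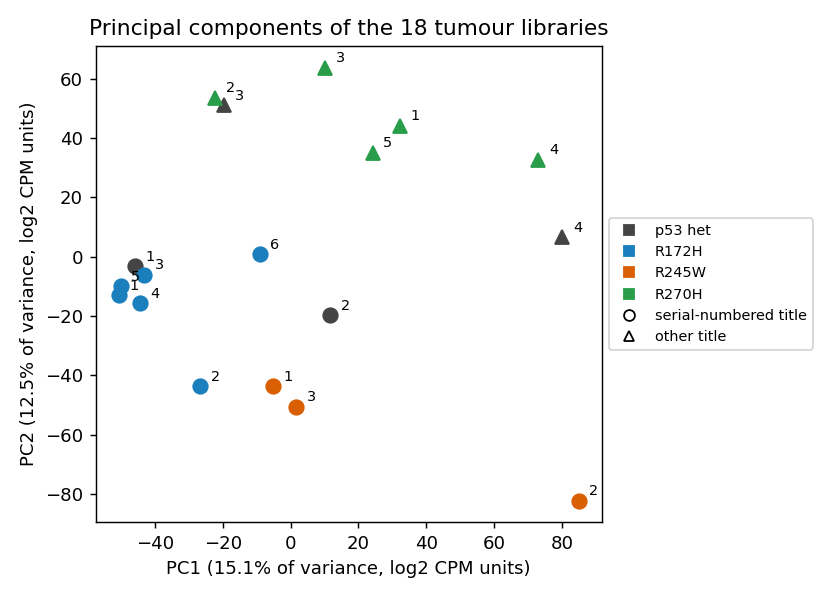
Principal components of log2 CPM of the 18 tumour libraries, PC1 on the horizontal and PC2 on the vertical axis, 1 point per library with its replicate number. Colour gives the genotype and shape the kind of title (with or without a serial number). The R270H libraries lie between 32.7 and 63.8 on PC2, and p53 het 3, whose title also lacks a serial number, lies at 51.1.

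Trp53 itself (chromosome 11, 69580359 to 69591873, GRCm38) was read at 21.7 ± 7.59 CPM in p53 het (n = 4), 49.0 ± 13.6 CPM in R172H (n = 6), 64.8 ± 10.3 CPM in R245W (n = 3) and 36.4 ± 11.2 CPM in R270H tumours (n = 5). Each R172H and R245W library lay above all 4 p53 het libraries. By design p53 het mice have a lost allele where the others have a missense one. The labels do not give the alleles left in each tumour, so more reads need not mean more per allele. In an exact two-sided permutation test of log2 CPM, Trp53 was higher in R172H than in p53 het tumours (p = 0.00476, the smallest that 210 splits can give, 0.0286 adjusted over the 6 contrasts). The other tests against p53 het did not pass that adjustment. For R245W the exact p was 0.0286, the smallest that its 35 splits can give (adjusted 0.0714). For R270H it was 0.0556 (exact test, adjusted 0.0833). Among mutants the exact p was 0.0357 for R245W against R270H, 0.131 for R245W against R172H and 0.113 for R270H against R172H (adjusted 0.0714, 0.131 and 0.131). Adjusted over all genes in edgeR, none of the 3 log2 folds against p53 het passed: 1.17 ± 0.27 in R172H (adjusted p = 0.106), 1.57 ± 0.30 in R245W (adjusted p = 0.0744) and 0.74 ± 0.27 in R270H (adjusted p = 0.295). Against p53 het 1 and 2 alone the log2 folds were 1.07 ± 0.36 (adjusted p = 0.577) and 1.48 ± 0.40 (adjusted p = 0.327). R270H against p53 het 3 and 4 gave 0.83 ± 0.32 (adjusted p = 0.408). DESeq2 called the R172H and R245W differences (adjusted p = 0.00661 and 0.00101), as did edgeR without p53 het 2 (0.0309 and 0.0341). Removal of the GC trend called the one in R245W (0.0352). Over all alternatives the adjusted p ran from 0.00661 to 0.594 in R172H, from 0.00101 to 0.327 in R245W and from 0.210 to 0.554 in R270H.

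**Figure D2:**
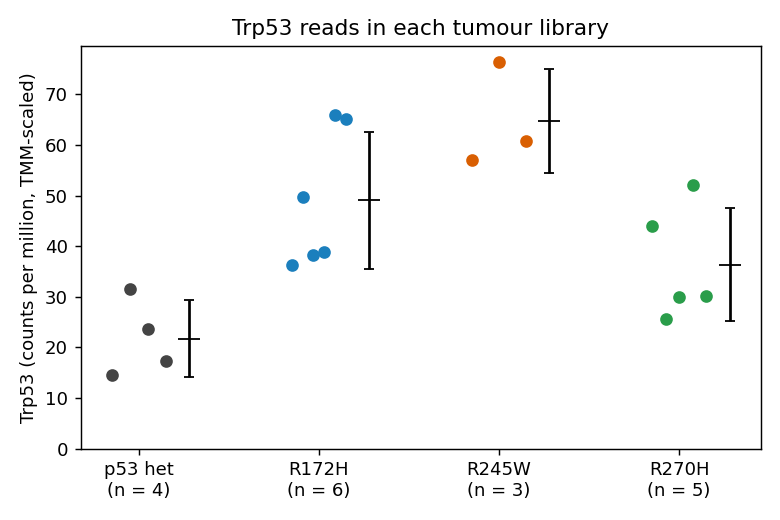
Trp53 in CPM (TMM-scaled) in each tumour library, 1 point per library, with the group mean and standard deviation beside the points. Every R172H and R245W library lies above the highest p53 het library, at 31.6 CPM.

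Among the genes that p53 activates, Cdkn1a, an inhibitor of the cell cycle, was read at 40.2 ± 21.7, 39.5 ± 17.0, 86.4 ± 22.5 and 47.2 ± 27.9 CPM in p53 het, R172H, R245W and R270H tumours. Mdm2, which marks p53 for degradation, was read at 51.6 ± 12.7, 51.6 ± 2.72, 52.3 ± 6.43 and 70.7 ± 19.2 CPM. Neither passed in any of the 6 contrasts (smallest adjusted p 0.314 for Cdkn1a and 0.136 for Mdm2). The list of 24 p53 target genes passed no contrast. Its smallest adjusted p in camera, 0.104, was reached by R172H against p53 het (5 members above 0, 19 below) and by R270H against R172H (19 above, 5 below).

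R172H tumours, compared with p53 het, had less RNA from the unfolded protein response, the interferon response and neutrophils in camera with its preset correlation. With an estimated correlation none of the 3 lists passed (adjusted p = 0.994 each), nor did any in the directional test of fry. The 18 genes of the unfolded protein response, which restores protein folding in the endoplasmic reticulum, had 16 members below 0. Chac1, induced by this response, had a log2 fold of -1.87 ± 0.60 and Xbp1, one of its transcription factors, of -0.59 ± 0.22. Of 21 interferon-response genes 17 lay below 0, among them Isg15 (log2 fold -1.72 ± 0.73) and Bst2 (-1.06 ± 0.47). All 14 neutrophil and granulocyte genes lay below 0, led by Chil3 (-1.79 ± 0.89) and Cxcr2, a chemokine receptor (-1.47 ± 0.76). No member of these 3 lists passed on its own, over all genes or adjusted over the list alone. With the preset correlation the adjusted p was 2.31e-04, 0.00246 and 0.0194. Against p53 het 1 and 2 alone their adjusted p was 1.10e-04, 0.00137 and 1.33e-04. The interferon list lost its call without p53 het 2 (adjusted p = 0.302), and the granulocyte list without p53 het 1 (0.345), p53 het 2 (0.0805), R172H 2 (0.0759) or R172H 4 (0.0532).

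A further 10 lists passed camera in R172H against all 4 p53 het tumours but not against p53 het 1 and 2 alone. None of the 10 passed with an estimated correlation (adjusted p = 0.994 each). The proteasome, which degrades tagged proteins, was lower (23 of 25 members below 0; Psmb5 -1.20 ± 0.35, Psma7 -0.74 ± 0.25; adjusted p = 1.17e-04 against all 4 and 0.275 against 1 and 2). MYC and ribosome biogenesis was lower (18 of 20; 0.00186 and 0.0913), with Gnl3, a nucleolar GTPase, at -0.93 ± 0.22. Oxidative phosphorylation was lower (20 of 25; 0.00669 and 0.916, with the direction turned), with Ndufa4, a respiratory chain subunit, at -1.40 ± 0.37. Non-polyadenylated RNAs were lower (14 of 18; 0.0454 and 0.452). Higher were endothelial genes (14 of 15 above 0; Erg 0.51 ± 0.18, Cdh5 0.82 ± 0.34; 3.21e-04 and 0.151), Notch genes (10 of 11; Hes1, a Notch target, 1.13 ± 0.34; 0.00845 and 0.0913) and osteoclast genes (9 of 14; Nfatc1 1.07 ± 0.48, Ostm1 -0.49 ± 0.32; 0.0102 and 0.112). Immediate early genes were also higher (15 of 16; Egr1 2.42 ± 0.80, Nr4a1 2.16 ± 0.75; 0.0124 and 0.0676), as were reported targets of mutant p53 (15 of 18; Pdgfrb 0.89 ± 0.24, Kmt2d 0.46 ± 0.20; 0.0293 and 0.189) and posterior Hox genes (9 of 13; Hoxb9 -2.46 ± 1.21, Hoxa13 1.99 ± 1.46; 0.0486 and 0.557, with the direction turned). Over all genes 1 member passed, the signal recognition particle RNA gene Rn7s2. Adjusted over the list alone Gnl3, Ndufa4, Hes1 and Pdgfrb passed, with Rn7s2 and Rn7s1 among the non-polyadenylated RNAs. Without p53 het 4 the calls of the endothelial (0.0758), MYC (0.0813), Notch (0.0561), osteoclast (0.718), mutant p53 target (0.0604) and non-polyadenylated lists (0.0605) ended. Without p53 het 3 those of oxidative phosphorylation (0.603), immediate early (0.0750), posterior Hox (0.861), mutant p53 target (0.0607) and non-polyadenylated genes (0.165) ended. Without p53 het 1 the Notch (0.124) and immediate early lists (0.114) lost theirs, and without p53 het 2 the osteoclast (0.0827) and non-polyadenylated lists (0.0765). Without R172H 6 this held for the immediate early (0.248), mutant p53 target (0.0683) and non-polyadenylated lists (0.0914), and without R172H 3 for the mutant p53 target list (0.0611). Leaving out R172H 1, R172H 4, R172H 5 or R270H 4 also ended the call of non-polyadenylated RNA (0.114, 0.0618, 0.0635 and 0.0520). The posterior Hox call ended in 10 of 18 such fits. The proteasome list kept its call in all 18.

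Gene by gene, 16 of 20616 genes passed in R172H against p53 het, 1 higher and 15 lower, of which 2 are protein-coding. Tacr1, the receptor of the neuropeptide substance P, rose to 1.76 ± 0.449 CPM from 0.271 ± 0.107 (log2 fold 2.67 ± 0.46, adjusted p = 0.0440). Gtf2f2, a subunit of the general transcription factor TFIIF, fell to 10.7 ± 1.79 CPM from 22.4 ± 4.38 (log2 fold -1.07 ± 0.19, adjusted p = 0.0440). The other named genes make small or antisense RNAs. Rny3, a Y RNA, fell by 5.83 ± 0.96 on the log2 scale (16.9 against 959 ± 1434 CPM, adjusted p = 0.0405). Rn7s2 fell by 5.31 ± 0.85 (0.420 against 16.6 CPM, adjusted p = 0.0405) and Rn7s6 by 5.15 ± 0.91 (0.331 against 11.8 CPM, adjusted p = 0.0440). BC018473, annotated as antisense, fell by 7.12 ± 1.23 (0.10 against 14.7 ± 25.9 CPM, adjusted p = 0.0440). The strand setting of the counting is not given, so which strand its reads came from is uncertain. Of the 16 genes, 8 had no overlap between the groups, against 2.03% of all tested genes (0.952% by chance). Genes chosen by a low p tend not to overlap, here and in the contrasts below, so this adds no support. Against p53 het 1 and 2 alone 4 genes passed, 2 of them among the 16. Of the named genes only BC018473 did (adjusted p = 0.0219; Tacr1 0.223, Gtf2f2 0.352, Rn7s2 0.679, Rny3 0.685, Rn7s6 0.945). The count moved from 16 to 166 without p53 het 1, 134 without p53 het 2, 3 without p53 het 3, 10 without R245W 2, 9 without R270H 1 and 7 without R172H 6. It was 0 without any one of the other 12 libraries, and 0 with limma voom. DESeq2 called 307 genes, and 2527 genes had an unadjusted p under 0.05 in edgeR. Each named gene lost its call in 13 or more of the 18 leave-one-out fits, with adjusted p from 0.137 to 0.179 without R172H 4. Without p53 het 1 the log2 fold of BC018473 was -4.12. Without p53 het 3 that of Rny3 was -3.94, of Rn7s6 -3.96 and of Rn7s2 -4.68.

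R245W tumours, compared with p53 het, held less RNA of T and NK cells, of the interferon response and of fibroblasts in camera with its preset correlation. None of these lists passed with an estimated correlation (adjusted p = 0.994 each), and no member passed over all genes. Of 16 T and NK cell genes 14 lay below 0, and Cd8b1, part of the CD8 co-receptor, was read at 0.324 ± 0.295 CPM against 2.64 ± 1.76 (log2 fold -2.99 ± 0.72). All 21 interferon-response genes lay below 0, with Bst2 at -1.81 ± 0.60 and Isg15 at -2.13 ± 0.94. Of 16 fibroblast genes 15 lay below 0. Lum, a proteoglycan of the collagen matrix, was read at 19.8 ± 14.2 CPM against 268 ± 198 (log2 fold -3.76 ± 1.19). Dcn, another such proteoglycan, had a log2 fold of -3.32 ± 1.15, and Postn, a matrix protein, of -3.14 ± 1.12. The unfolded protein response was lower too (16 of 18 members below 0; Xbp1 -0.94 ± 0.27, Creld2 -0.96 ± 0.40). This list too had 0.994 with an estimated correlation, and no member passed over all genes; adjusted over the list alone Cd8b1 and Xbp1 did. In camera the 4 lists had adjusted p = 7.14e-06, 1.17e-04, 0.00845 and 0.00831. Against p53 het 1 and 2 alone they had 5.62e-06, 1.24e-04, 0.00595 and 0.00316. The fibroblast call ended without p53 het 2 (0.115) or R245W 2 (0.0746), and that of the unfolded protein response without p53 het 2 (0.0625) or R245W 3 (0.159).

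In the same comparison erythroid genes were higher (12 of 13 members above 0; Hba-a1, an alpha globin, 2.07 ± 1.05 and Alas2, an enzyme of heme synthesis, 1.13 ± 0.60; adjusted p = 0.00777, and 0.994 with an estimated correlation). Proteasome (20 of 25 below 0; Psma4 -0.76 ± 0.27, Psmd11 0.44 ± 0.17; 0.0140) and oxidative phosphorylation genes (21 of 25 below 0; Ndufa4 -1.19 ± 0.45, Cox5a -0.56 ± 0.25; 0.0221) were lower, and neither list passed with an estimated correlation (adjusted p = 0.994 each). No member of these lists passed, over all genes or adjusted over the list alone. Against p53 het 1 and 2 alone the adjusted p was 0.112 for erythroid, 0.819 for proteasome and 0.942, with the direction turned, for oxidative phosphorylation genes. The proteasome call ended without p53 het 3 (0.0633), p53 het 4 (0.163) or R245W 3 (0.488), and that of oxidative phosphorylation without p53 het 3 (0.608), R245W 1 (0.107) or R245W 3 (0.269).

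Among single genes, 15 passed in R245W against p53 het, 7 higher and 8 lower, of which 5 are protein-coding. Ndufs5, a subunit of respiratory complex I on chromosome 4 (123712710 to 123718202), fell to 1.11 ± 0.493 CPM (n = 3) from 17.6 ± 6.76 (n = 4), a log2 fold of -3.97 ± 0.37 (adjusted p = 5.15e-05). Rhbdl2, a membrane protease encoded next to it (123787874 to 123829904), fell to 5.30 ± 2.35 from 36.2 ± 12.1 CPM (log2 fold -2.77 ± 0.40, adjusted p = 0.00708). Zcchc17, an RNA-binding protein on the same chromosome (130315383 to 130359943), fell to 19.4 ± 0.935 from 36.1 ± 6.89 CPM (-0.90 ± 0.16, adjusted p = 0.0395). Foxo1, a transcription factor of insulin signalling (chromosome 3, 52268336 to 52353221), rose to 109 ± 35.7 from 24.7 ± 6.74 CPM (log2 fold 2.14 ± 0.37, adjusted p = 0.0305). Rpl34, a ribosomal protein gene with processed copies in the genome that can share its reads, fell to 21.9 ± 12 from 160 ± 84.0 CPM (-2.88 ± 0.47, adjusted p = 0.0202). All 15 genes had no overlap between the groups, against 8.77% of all tested genes (5.71% by chance), which a choice by low p favours. Against p53 het 1 and 2 alone 9 genes passed, 8 of them among the 15. These included Ndufs5 (log2 fold -4.27, adjusted p = 8.96e-06) and Rhbdl2 (-3.11, 0.0119) but not Foxo1 (2.11, 0.295), Rpl34 (-2.28, 0.158) or Zcchc17 (-0.67, 0.301). Ndufs5 kept its call in all 18 leave-one-out fits, and Rhbdl2 lost it without R245W 1 (0.0739) or R245W 2 (0.0583). Rpl34 lost it without p53 het 3 (0.0524), R245W 1 (0.123) or R245W 3 (0.144). Foxo1 lost it in 10 fits (largest adjusted p 0.139, without R245W 2) and Zcchc17 in 15 (0.160, without p53 het 3). The count of 15 became 29 without p53 het 1, 30 without p53 het 2, 8 without p53 het 3 and 5 without R245W 1, and DESeq2 called 371 genes.

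**Figure D3:**
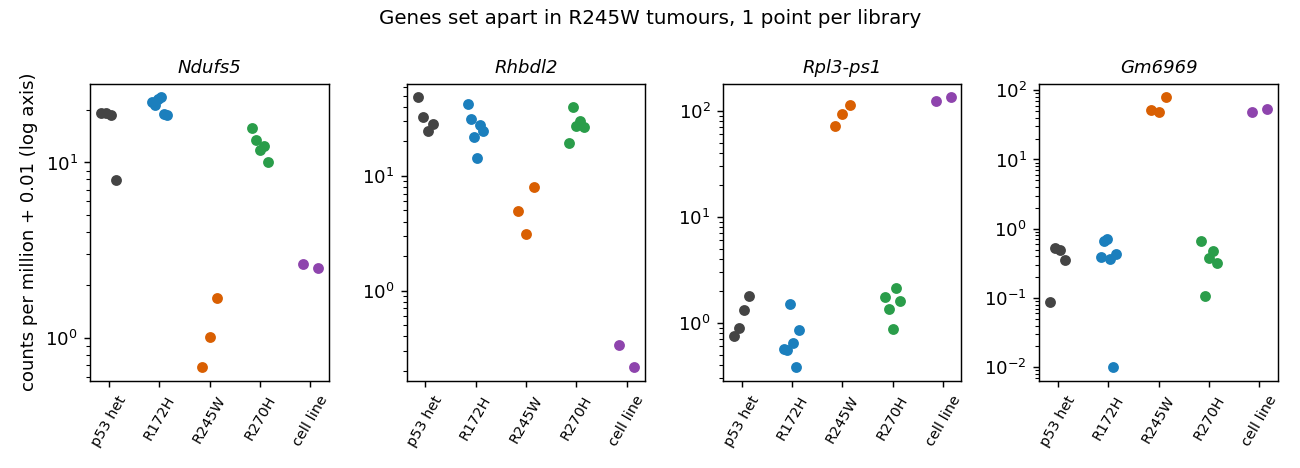
CPM plus 0.01 (log axis) of Ndufs5, Rhbdl2 and the pseudogenes Rpl3-ps1 and Gm6969, which were picked after their values were seen, in each tumour library and in both libraries of cell line 14. In all 4 panels the R245W tumours lie apart from the other 15 tumours, and the cell line lies on their side.

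R270H tumours, compared with p53 het, had more erythroid and neutrophil RNA and less of the antigen presentation genes in camera with its preset correlation. None of these lists passed with an estimated correlation (adjusted p = 0.994 each), and without R270H 5 the erythroid and neutrophil calls ended (0.0809 and 0.648). All 13 erythroid genes lay above 0, with Rhag, a red cell membrane protein, at a log2 fold of 5.40 ± 1.58 and Klf1, an erythroid transcription factor, at 3.74 ± 1.18. Of these, 9 members passed adjusted over the list alone and none over all genes. Of 14 neutrophil and granulocyte genes 13 lay above 0, with S100a9, a calcium-binding protein of neutrophils, at 4.06 ± 1.43 and Ltf, lactoferrin, at 4.44 ± 1.59. All 16 antigen presentation genes lay below 0; Tap2, a peptide transporter (-0.93 ± 0.27), passed adjusted over the list alone, and B2m, the light chain of MHC class I, had -1.11 ± 0.44. Endothelial genes were higher (12 of 15 above 0; Erg 0.52 ± 0.18, Cldn5 0.76 ± 0.38) and those of T and NK cells lower (15 of 16 below 0; Cd8b1 -1.08 ± 0.55, Cd4 -1.14 ± 0.76). In camera the adjusted p was 6.25e-04 for erythroid, 0.0273 for neutrophil, 0.00777 for antigen presentation, 0.0158 for endothelial and 0.0357 for T and NK cell genes (adjusted p = 0.994 each with an estimated correlation). With the title code as a covariate it was 1.92e-04, 1.92e-04, 0.00875, 5.86e-05 and 0.267. It was 0.0997, 0.662, 0.0955, 0.805 and 0.0481 against p53 het 1 and 2 alone, which carry the other kind of title, so that only the T and NK cell list passed. The blood cell RNA was uneven: in R270H 5 the mean log2 CPM was 5.94 for the erythroid and 6.11 for the neutrophil list, against at most 2.80 and 3.22 in the other R270H tumours. The neutrophil call also ended without p53 het 3 (0.171), p53 het 4 (0.193) or R270H 2 (0.0567). The antigen presentation call ended without p53 het 3 (0.111) or R270H 4 (0.112), and the endothelial call without p53 het 1 (0.0570), p53 het 4 (0.645) or R270H 1 (0.0570). The T and NK cell call ended without p53 het 1 (0.128), p53 het 2 (0.0680), p53 het 3 (0.274), R270H 3 (0.254) or R270H 4 (0.253).

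No single gene passed between R270H and p53 het tumours in edgeR (smallest adjusted p 0.0791), while 2364 genes had an unadjusted p under 0.05, where about 1031 are expected by chance. DESeq2 called 329 genes and limma voom 1. The 5 genes with the lowest p, none of which passed, were Tlx1, a homeobox transcription factor (4.47 ± 3.67 against 0.0578 ± 0.0444 CPM; log2 fold 6.11 ± 0.98), Mrps34, a mitochondrial ribosomal protein (-1.78 ± 0.30), Gnas, a G protein subunit (-1.73 ± 0.30), Pigt, an enzyme of GPI anchors (-1.23 ± 0.22), and the pseudogene Rps3a3 (-7.50 ± 1.34), whose reads can come from its parent gene. The adjusted p of each was 0.0791. Against p53 het 3 and 4 alone, whose titles also lack a serial number, 4 genes passed in edgeR. Tlx1 and Gnas were not among them (log2 folds 5.81 and -1.14, adjusted p = 0.165 and 0.252). Against p53 het 1 and 2 alone 94 genes passed. Leaving out p53 het 3, R172H 6 or R270H 5 gave 21, 6 and 2 genes, and leaving out any other library 0.

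Between mutants, R245W tumours differed from R172H tumours in MYC and ribosome biogenesis genes, all 20 of which lay above 0 in R245W. This list and the others of this comparison passed camera with its preset correlation and not with an estimated one (adjusted p = 0.994 each). Myc, a transcription factor that drives growth, was read at 249 ± 131 CPM (n = 3) against 84.6 ± 19.8 (n = 6; log2 fold 1.56 ± 0.40), Ncl, the nucleolar protein nucleolin, at 347 ± 39.5 against 185 ± 20.5 CPM (0.90 ± 0.21). Polr1a, a subunit of RNA polymerase I, had 0.88 ± 0.23. Of the list, 7 members passed adjusted over the list alone and none over all genes. Fibroblast genes were lower (15 of 16 below 0; Lum -4.47 ± 1.20, Postn -3.92 ± 1.14, both past the threshold adjusted over the list alone), as were T and NK cell genes (14 of 16; Gzmb, a protease of cytotoxic cells, -5.49 ± 1.65, Cd8b1 -1.93 ± 0.66). Neutrophil (14 of 14; Prtn3 3.24 ± 1.25, Elane 3.89 ± 1.63) and erythroid genes (13 of 13; Alas2 1.01 ± 0.54, Slc4a1 2.49 ± 1.33) were higher. The DNA replication list was higher (22 of 24 above 0; Mcm5 0.72 ± 0.31, Mcm7 0.71 ± 0.31). The endothelial (13 of 15 below 0; Vwf -1.40 ± 0.41, past the threshold adjusted over the list alone) and osteoclast lists (13 of 14 below 0; Clcn7 -0.57 ± 0.34, Car2 -1.33 ± 0.93) were lower. In camera the adjusted p was 9.04e-08 for MYC, 1.17e-04 for fibroblast, 1.17e-04 for T and NK cell and 1.96e-04 for neutrophil genes. It was 0.00139 for erythroid, 0.00845 for DNA replication, 0.0185 for endothelial and 0.0220 for osteoclast genes. Without R245W 2 the DNA replication list turned direction (adjusted p = 0.904), and the osteoclast list, in the same direction, lost its call (0.863). Without R245W 3 the neutrophil (0.0695) and endothelial calls (0.310) ended, the latter also without R172H 3 (0.0652).

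Both groups carry serial-numbered titles. In edgeR 32 genes passed between R245W and R172H, 24 higher and 8 lower in R245W, and 10 of them protein-coding. All were without overlap, against 5.60% of all tested genes (2.38% by chance). Hmga1b, a chromatin protein gene that is a near copy of Hmga1, rose to 4.37 ± 3.0 from 0.163 ± 0.0774 CPM (log2 fold 4.69 ± 0.78, adjusted p = 0.0168). Lmo1, a transcription cofactor, rose to 10.8 ± 16.7 from 0.646 ± 0.115 CPM (4.05 ± 0.72, 0.0251) and Prss41, a serine protease, to 3.61 ± 5.47 from 0.0206 ± 0.0354 CPM (7.15 ± 1.27, 0.0251). The antisense gene BC018473 (6.86 ± 1.24, 0.0287) and the pseudogene BC002163 (5.56 ± 1.06, 0.0435) were also higher. The source of the reads of both is uncertain. Ndufs5 fell by 4.20 ± 0.37 on the log2 scale (1.11 against 20.6 ± 1.86 CPM, adjusted p = 1.21e-05), Rhbdl2 by 2.31 ± 0.38 (0.0153), Arhgap32, a GTPase regulator, by 2.90 ± 0.54 (5.56 against 41.5 CPM, 0.0370) and Adhfe1, a mitochondrial dehydrogenase, by 2.10 ± 0.37 (0.0244). DESeq2 called 352 genes, 29 of them among the 32, and limma voom 119. In a fit of protein-coding genes alone Ndufs5 was the 1 gene left, and Rhbdl2 and Hmga1b (0.0618 each), Lmo1 (0.0795), Prss41, Arhgap32 and Adhfe1 (0.0892 each) lost their calls. The count fell to 14 without R172H 1, R172H 6 or R245W 2, 15 without R172H 4, 18 without R245W 1 and 21 without R245W 3. Ndufs5 kept its call in all 18 leave-one-out fits. Rhbdl2 lost it without R245W 1 (0.0955) or R245W 2 (0.101), Adhfe1 without R172H 4 (0.0560), R245W 1 (0.108) or R245W 2 (0.135). Hmga1b lost its call without R172H 1 (0.0502), R172H 4 (0.0560), R172H 6 (0.0535) or R245W 2 (0.101). Without R245W 2 neither Prss41 (log2 fold 4.17, adjusted p = 0.468) nor Lmo1 (0.81, 0.731) passed; Prss41 lost its call in 6 of 17 fits, and of 18 fits Lmo1 lost it in 7, BC018473 in 9, Arhgap32 in 10 and BC002163 in 13.

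R245W tumours, set against R270H tumours, were lower in the interferon response (20 of 21 genes below 0), T and NK cell (14 of 16) and fibroblast lists (14 of 16). None of the 3 passed with an estimated correlation (adjusted p = 0.994 each). Bst2, which tethers viruses to the cell surface, was read at 14.7 ± 1.07 against 61.9 ± 29 CPM (log2 fold -2.08 ± 0.59), Rsad2 had -1.62 ± 0.75, Cd8b1 -1.91 ± 0.68, Cd3g -2.00 ± 0.88, Lum -3.31 ± 1.14 and Cd34 -0.72 ± 0.27. Camera with its preset correlation gave adjusted p = 0.00366, 0.0152 and 0.0220 and, with the title code as a covariate, 0.00226, 0.00705 and 0.0155. No member of the 3 lists passed over all genes or adjusted over the list alone. The proteasome (22 of 25 below 0; Psma3 -0.87 ± 0.24, past the threshold adjusted over the list alone; Psma2 -0.79 ± 0.28; adjusted p = 0.00447) and epidermis lists (all 7 measured members below 0; Dmkn 0.0450 against 8.27 ± 15 CPM, Krtdap without a read in R245W; 5 past the threshold adjusted over the list alone; adjusted p = 0.0361) were lower too. Both had adjusted p = 0.994 with an estimated correlation and lost their calls with the title code as a covariate (0.529, with the direction turned, and 0.489). Without R245W 2 the calls of the interferon (0.0736), T and NK cell (0.268) and fibroblast lists (0.130) ended, and without R270H 2 those of the latter 2 (0.0519 and 0.0597). The T and NK cell call also ended without R245W 1 (0.0935) or R270H 5 (0.0765), the proteasome call without R245W 3 (0.204), and the epidermis call without p53 het 4 (0.0605), R270H 3 (0.109) or R270H 4 (0.304).

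By gene, 255 genes passed between R245W and R270H, 156 higher and 99 lower in R245W, of which 164 are protein-coding. No overlap was seen in 253 of them, against 13.5% of all tested genes (3.57% by chance). Tgfb1, a growth factor of the TGF-beta family, rose to 171.8 ± 42.8 from 70.8 ± 11 CPM (log2 fold 1.28 ± 0.23, adjusted p = 0.0151) and Kmt2d, a histone methyltransferase, to 378 ± 73.3 from 189 ± 46.9 CPM (1.0 ± 0.22, 0.0367). Rbbp8, which starts the repair of DNA breaks, fell to 23.2 ± 3.26 from 44.8 ± 4.88 CPM (-0.95 ± 0.20, 0.0299). Prss41 was higher (6.85 ± 1.35, 0.0259), and so were the antisense gene BC018473 (6.92 ± 1.36, 0.0259) and 3 annotated pseudogenes, Rps3a3 (7.33 ± 1.35, 0.0180), BC002163 (6.69 ± 1.22, 0.0177) and Hist1h2al, with 28.5 ± 18.8 CPM and no read in any R270H library (0.0180). Tlx1 was lower (-5.39 ± 1.06, 0.0259), as were Ly6d, a surface protein of epithelial and B cells (-4.91 ± 1.12, 0.0397), and the small RNA genes Rn7s6 (-5.18 ± 1.23, 0.0482), Mir703 (-5.14 ± 0.74, 0.00361) and Snora69 (-4.27 ± 0.96, 0.0374). With the title code as a covariate 8 genes passed, 6 of them among the 255. Of the genes named here BC002163 alone passed (0.0155). Tgfb1 then had a log2 fold of 0.98 (adjusted p = 0.466) and Rn7s6 turned direction (0.72). The count became 48 without R245W 3, 59 without R245W 1, and 127 without R245W 2. It was 61 without R270H 3, 90 without R270H 2, 96 without R270H 1, and 144 without R270H 5. It was 384 without p53 het 3 and 411 without p53 het 2, and DESeq2 called 1201 genes. Hist1h2al, BC002163 and Mir703 kept their calls in all 18 leave-one-out fits, and Rps3a3 lost its own without R270H 3 (0.0583). Tgfb1 lost it without R245W 2 (0.0501) or R245W 3 (0.0685). Prss41 lost it without R245W 2 (0.140, with a log2 fold of 3.87), R270H 1 (0.0592), R270H 2 (0.0533) or R270H 3 (0.0662), and Tlx1 without R245W 1 (0.0557), R245W 2 (0.0650), R245W 3 (0.111) or R270H 3 (0.0539). Without R245W 3 none of BC018473 (0.0685), Rbbp8 (0.138), Kmt2d (0.158), Ly6d (0.136), Snora69 (0.151) and Rn7s6 (0.166) passed, and these 6 lost their calls in 5, 6, 7, 8, 7 and 15 fits.

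R270H and R172H tumours differed in the most genes, 1088, of which 703 were higher and 385 lower in R270H. This rank did not hold with the title code as a covariate, where 1 of these genes was left. Of the 1088, 788 are protein-coding, and 814 had no overlap between the groups, against 7.69% of all tested genes (0.433% by chance). The 6 gene lists below passed camera with its preset correlation and none with an estimated one (adjusted p = 0.994 each). All 14 neutrophil genes lay above 0 in R270H, 5 of them past the threshold over all genes and 12 adjusted over the list alone. S100a9 rose to 97.4 ± 173 from 2.11 ± 2.82 CPM (log2 fold 5.54 ± 1.30, adjusted p = 0.0234), and Chil3 to 26.7 ± 38.1 from 2.16 ± 1.5 CPM (3.62 ± 0.90, 0.0294). All 13 erythroid genes lay above 0, with 4 past the threshold over all genes and 10 adjusted over the list alone (Rhag 5.49 ± 1.33, 0.0262; Klf1 3.6 ± 0.99, 0.0437). In the proteasome 22 of 25 genes were above 0, and Psma3 (0.90 ± 0.19, 0.0168), Psma7 (0.99 ± 0.23, 0.0243) and Psma2 (0.79 ± 0.22, 0.0488) rose, with 11 past the threshold adjusted over the list alone. Of 20 MYC and ribosome biogenesis genes 18 were above 0, and Ncl (0.79 ± 0.19, 0.0239), Gnl3 (0.90 ± 0.21, 0.0243) and Nop16 (0.73 ± 0.19, 0.0355) rose, 5 adjusted over the list alone. Epidermis genes were higher (6 of 7; Dmkn 5.89 ± 1.28, 0.0176; Krtdap 7.49 ± 13.1 against 0.00744 ± 0.0182 CPM, 0.0214; 3 over all genes, 5 adjusted over the list alone). Osteoclast genes were lower (12 of 14). Nfatc1, the master regulator of osteoclasts, fell to 104 ± 46.3 from 343 ± 79.2 CPM (-1.71 ± 0.45, 0.0366) and was the 1 member past the threshold over all genes and adjusted over the list alone. Camera gave adjusted p = 1.20e-04 for neutrophil, 0.00372 for erythroid, 1.17e-04 for proteasome, 0.0158 for MYC, 0.0293 for epidermis and 0.0378 for osteoclast genes. With the title code as a covariate the neutrophil and erythroid lists passed (7.61e-08 and 6.88e-04). The proteasome (0.832, with the direction turned), MYC (0.687), epidermis (0.508) and osteoclast lists (0.839) did not. The covariate rests on the p53 het tumours alone. Of these, p53 het 1 was high in S100a8 (18.8 CPM, against 1.70 to 3.10 CPM in the others), which raises the adjusted neutrophil difference. The smaller p of the neutrophil list is thus no sign that it stands apart from a batch. Without R270H 5 the erythroid call ended (0.116). Without R270H 4 those of MYC (0.219), epidermis (0.304) and osteoclast genes (0.398) ended. The epidermis list also lost its call without R270H 3 (0.109) or p53 het 4 (0.0558), osteoclast genes without R172H 4 (0.0736). The mean log2 CPM of the epidermis list was 4.75 in R270H 4 and 2.56 in R270H 3, against at most -0.65 in the other R270H tumours. Of the members named here Psma3 kept its call in all 18 leave-one-out fits. Psma2 lost its call in 13 of them, Klf1 in 9, Nop16 and Nfatc1 in 8 each, Psma7 and Chil3 in 5, Rhag and Gnl3 in 4, S100a9 in 3, Ncl in 2 and Dmkn in 1, and Krtdap in 2 of 15. Without R270H 5 those of S100a9 (0.0873), Chil3 (0.115), Rhag (0.130) and Klf1 (0.467) ended, with log2 folds of 3.26, 2.17, 2.94 and 0.87, and without R270H 4 those of Psma7 (0.0615), Psma2 (0.117), Ncl (0.0528), Gnl3 (0.0602) and Dmkn (0.0598, with a log2 fold of 3.56). Without R270H 1 those of Nop16 (0.0988) and Nfatc1 (0.0836) ended, and without R172H 2 that of Krtdap (0.0720).

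Among other genes that differ between R270H and R172H, Tgfb1 (70.8 ± 11 against 147 ± 25.1 CPM; log2 fold -1.06 ± 0.20, adjusted p = 0.0108) and Pmepa1, induced by TGF-beta (-1.67 ± 0.37, 0.0189), fell, while Id3, an inhibitor of differentiation factors (0.92 ± 0.25, 0.0437), rose. The TGF-beta response list did not pass in camera (adjusted p = 0.985). Itgb1, the beta 1 integrin of matrix adhesion, rose to 894 ± 151 from 487 ± 69.8 CPM (0.88 ± 0.16, 0.00982), and its partner in the matrix, fibronectin Fn1, fell (-1.21 ± 0.34, 0.0442). Among genes whose groups did not overlap, the named ones with the largest log2 folds were Muc2, a secreted mucin (4.40 ± 1.03, 0.0230), Pdzk1ip1 (4.16 ± 0.97, 0.0234) and the small RNA genes Snora69 (5.07 ± 0.74, 0.00449), Rn7s6 (4.87 ± 0.89, 0.0107) and Rn7s2 (4.27 ± 0.80, 0.0113) upward. Downward they were Sod3, an extracellular superoxide dismutase (8.35 ± 3.59 against 45.8 ± 31.7 CPM; -2.45 ± 0.55, 0.0195), Cpxm1 (-2.34 ± 0.52, 0.0197), Whrn, a scaffold protein (-2.17 ± 0.44, 0.0151), P2rx2, an ATP-gated channel (-2.41 ± 0.65, 0.0405), and Mir5125 (-2.44 ± 0.37, 0.00489). With the title code as a covariate 1 of the 1088 genes passed and none of those named here. The log2 fold of Tgfb1 was then -0.76 (adjusted p = 0.587), of Itgb1 1.10 (0.454), of Rn7s6 -1.03 and of Rn7s2 -0.93, the last 2 with the direction turned. The count became 551 without R172H 1, 469 without R172H 3, 552 without R172H 4, and 712 without R172H 5. It was 472 without R270H 1, 540 without R270H 3, 621 without R270H 4 and 685 without R270H 5, and DESeq2 called 2243 genes. Tgfb1, Itgb1, Sod3, Whrn, Snora69, Rn7s6, Rn7s2 and Mir5125 kept their calls in all 18 leave-one-out fits. Muc2 lost its call without R270H 4 (0.222, with a log2 fold of 1.02), R172H 1 (0.0531) or R172H 3 (0.0512). Pdzk1ip1 lost it without R172H 1 (0.0540) or R172H 3 (0.0534), Cpxm1 without R270H 1 (0.0531) or R270H 3 (0.0502), and Pmepa1 without R270H 1 (0.050). P2rx2, Id3 and Fn1 lost theirs in 8, 10 and 11 fits (largest adjusted p 0.0936, 0.118 and 0.0981).

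Across all 4 genotypes 590 genes passed edgeR's test for any difference (4550 at an unadjusted p under 0.05). The count depended on the libraries and the method: it ran from 185 (without R270H 1) to 937 (without p53 het 1) in the leave-one-out fits, and was 330 with limma voom, 2513 with DESeq2, 241 among protein-coding genes alone and 19 with the title code as a covariate. No gene passed in the same direction in 2 of the 3 contrasts against p53 het, where independent lists would share 0.00034 higher and 0.00582 lower genes for R172H and R245W. As R270H had 0 called genes, its 2 overlaps were fixed at 0, and lists of 16 and 15 genes say little about shared changes. DESeq2's lists shared 69 (R172H and R245W), 26 (R172H and R270H) and 20 (R245W and R270H). These contrasts use the same 4 p53 het libraries. The log2 folds correlated across genes (which are not independent replicates) at r = 0.422, 0.352 and 0.322, and simulated mutants that differ in nothing from p53 het gave 0.499, 0.585 and 0.482, with no shared gene in any of 20 simulations. Their covariances, 0.294, 0.205 and 0.229, exceeded the simulated ones by 0.125, 0.0358 and 0.0601, and were -0.0449, -0.106 and -0.0908 when each contrast used its own pair of p53 het libraries. The simulations hold no title code, and R172H and R245W, with the largest excess, share a kind of title. Pairing p53 het 1 with 2 and 3 with 4 also follows the titles. These values therefore cannot tell shared changes from a batch.

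Of the 37 gene lists, 18 passed camera in none of the 6 contrasts. The nearest were adipocyte genes (lower in R172H than in p53 het tumours, adjusted p = 0.0662), macrophage genes (lower, same contrast, 0.0949), the TGF-beta response (higher, same contrast, 0.0955) and chondrocyte genes (lower in R245W than in R172H, 0.0961). The skeletal muscle list reached 0.0955 in R270H against p53 het, with a test pointing up while its median (-0.54) and mean (-0.47) lay below 0. The interferon list, tested upward in R270H against R172H (0.0597), likewise had a median of -0.12 and a mean of 0.04. The smallest adjusted p was 0.149 for hypoxia and glycolysis, 0.208 for inflammatory cytokines and NF-kB, 0.244 for mitosis, 0.248 for mevalonate and cholesterol synthesis and 0.30 for B and plasma cell genes. It was 0.341 for Wnt targets and feedback genes, 0.345 for Schwann cell, 0.510 for homologous recombination, 0.544 for epithelial-mesenchymal transition and invasion, 0.544 for lung epithelium (4 of 10 genes measured), 0.631 for osteoblast and osteocyte and 0.639 for mitochondrially encoded genes. Single members passed adjusted over the list alone but not over all genes. Smad7, an inhibitor of TGF-beta signalling, was higher in R172H than in p53 het tumours (log2 fold 0.98 ± 0.20, 0.0667 over all genes, 0.00252 over the list). Tnfrsf10b, a death receptor that p53 activates, was higher in R245W than in R172H (1.77 ± 0.38, 0.0976 and 0.00534). Sesn2, a p53 target of the stress response, was lower in R270H than in p53 het (-1.69 ± 0.34, 0.102 and 0.00225). Of the chondrocyte genes Comp, Snorc, Col9a2 and Col2a1 were lower in R245W than in R172H adjusted over the list alone (0.0469 each). The test of fry for change in either direction passed for reported targets of mutant p53 in R245W against R270H (adjusted p = 3.84e-07), R245W against R172H (0.00560) and R270H against R172H (0.00472). It also passed for p53 targets in R245W against R270H (0.00472), the TGF-beta response in R270H against R172H (0.00105) and R172H against p53 het (0.0319), and, both in R270H against R172H, epithelial-mesenchymal transition (0.0319) and the proteasome (0.0438). The either-direction test looks at the genes of a list alone. Contrasts with many called genes, such as R245W against R270H (255) and R270H against R172H (1088), thus favour a call. It was not repeated with the title code as a covariate or with libraries left out. No list passed the directional test of fry (smallest adjusted p 0.718).

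In cell line 14, siRNA against p53 lowered Trp53 from 94.9 CPM (95% Poisson interval 92.5 to 97.3) to 30.6 CPM (29.3 to 31.9), 32.2% of the control level. With 1 library per arm there is no test, and the values below are log2 ratios of CPM plus 1. Of the 24 p53 target genes 23 had less RNA after the knockdown (median -0.38, below all 10000 random lists of like expression), with Cdkn1a at 12.9 and 3.65 CPM (-1.57) and Mdm2 at 118 and 83.8 CPM (-0.49). All 21 interferon-response genes had less (median -0.55, below all random lists): Ifit3, an interferon-induced antiviral protein, was read at 84.2 and 36.3 CPM (-1.19), and Ifit3b and Slfn5 had -1.24 and -1.20. Chac1 (-1.22) and Atf3 (-1.04), both of the stress response of the endoplasmic reticulum, and the lysosomal Pld3 (-1.03) were also among the lowest. The list of the unfolded protein response, which holds Chac1 and Atf3, did not move (9 members lower, 9 higher, median -0.0094, percentile 40.0). At least 10 CPM in 1 library was reached by 9398 genes, of which 11 had a log2 ratio of -1 or less and 0 of 1 or more. The highest were Dpep1 (0.86), Mrgprf (0.81), Apcdd1 (0.78), Tmem119 (0.78), Gas1 (119 and 201 CPM, 0.76), Il1rl1 (0.75), Agt (0.72) and mt-Co3 (0.70). Genes of mitosis (24 of 25 higher, median 0.14), mevalonate and cholesterol synthesis (19 of 20, 0.21) and fibroblasts (15 of 16, 0.18) had medians above all random lists, as had osteoblast and osteocyte (0.20) and hypoxia and glycolysis genes (0.15). Of the 37 lists 16 lay outside the middle 95% of the random lists, 11 above and 5 below, so lying outside is not particular to the lists named. Among those below were non-polyadenylated RNAs (median -0.14), a list that varies with how RNA is prepared, and reported targets of mutant p53 (-0.15).

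The line was set beside the R245W tumours to see which of their differences move when Trp53 RNA is lowered; protein was not measured. The interferon list was lower in R245W than in p53 het tumours (all 21 genes below 0) in camera with its preset correlation, not with an estimated one (adjusted p = 0.994). In the line the interferon list was lower after the knockdown than in the control (median -0.55), where a return toward p53 het would be a rise. T and NK cell genes were lower in R245W tumours too, in camera with its preset correlation. The tumour value of the interferon list may thus follow the share of such cells, which in the line it cannot. This was not tested. Fibroblast genes, lower in R245W tumours (15 of 16), had more RNA after it (median 0.18). The tumour call likewise failed with an estimated correlation, and it ended without p53 het 2 (0.115) or R245W 2 (0.0746). This is a cell type list, which in a tumour can follow the share of fibroblasts and in the line cannot. The 2 values thus need not measure the same thing. Since 7 genes passed as higher and 8 as lower in R245W than in p53 het tumours, the 100 genes of lowest p in each direction were taken. Of 83 genes higher in R245W tumours with at least 10 counts in the line, 59 had less RNA after the knockdown (median log2 ratio -0.12, below all random lists), and of 86 lower in R245W tumours, 50 had more (0.04, percentile 99.9). Most of these genes did not pass in the tumours. Random lists do not copy genes that move together, and 16 of the 37 fixed lists also lay outside their middle 95%. With 1 library per arm the percentiles therefore lend little weight to a reversal by the knockdown. With the genes called by DESeq2 the medians were -0.11 and 0.03.

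**Figure D4:**
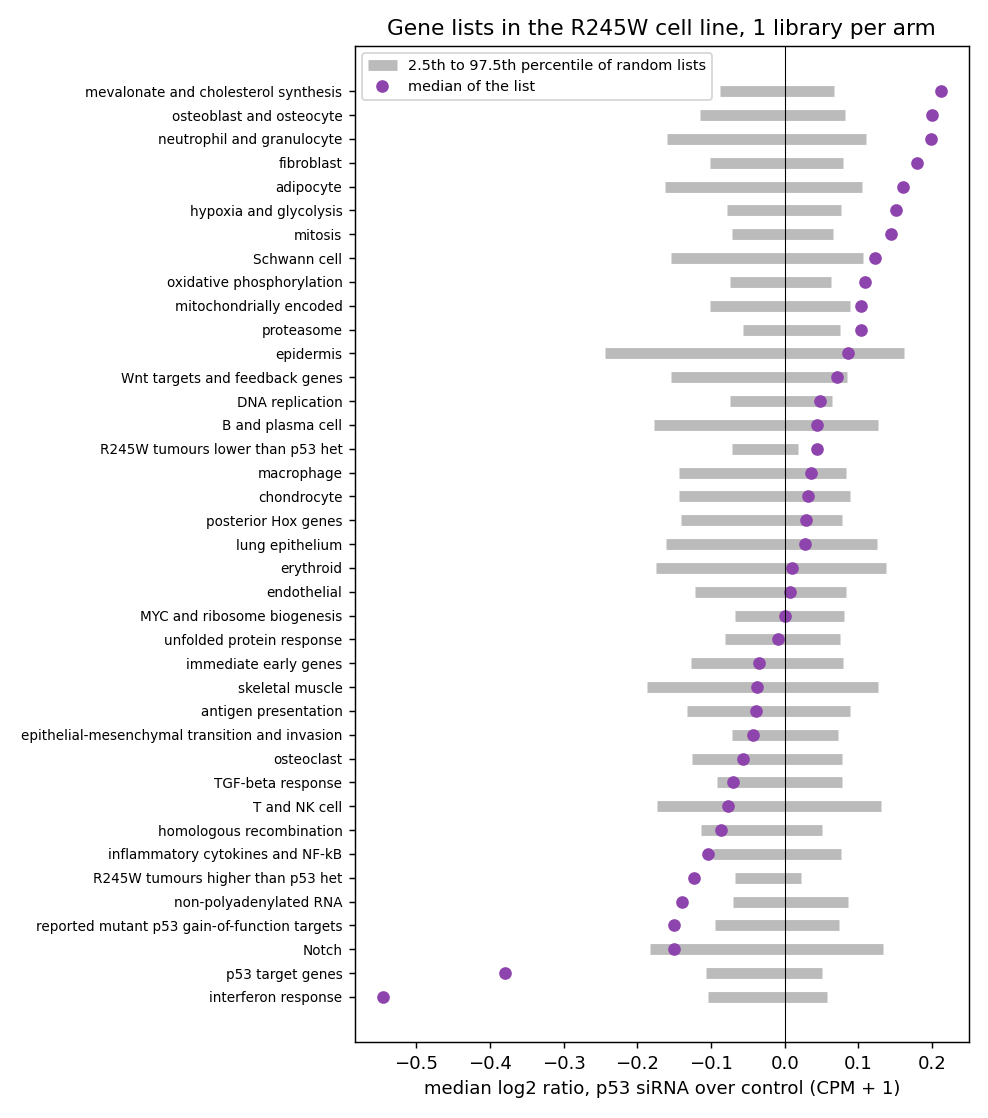
Median log2 ratio of CPM plus 1, p53 siRNA over control, for each gene list in cell line 14 (points), with the middle 95% of 10000 random lists of the same size and like expression (bars). The interferon response (-0.55) and p53 target genes (-0.38) lie lowest, and mevalonate and cholesterol synthesis (0.21) highest; there is 1 library per arm and no test.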

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

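The tests in this part were planned before their results were seen, with 3 exceptions: the tests of a batch marked by the titles were set after the principal components and the levels of some small RNAs in each library were seen, the 5 Mb window for neighbouring genes was set afterwards, and the test of reads shared with copies was limited, after its first result, to genes whose own change was large enough to move the summed reads. A library is listed here when its distance to the nearest other library of its group is unusually large against the range of the group. Of 528 groups of 4 to 6 libraries, 36 held such a library, and chance finds about 1 in 20 groups, here 26.4. The number after each item is that distance as a share of the range.

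Among p53 het tumours, p53 het 4 was lowest for osteoblast genes (0.887) and Ndufs5 (0.887) and highest for epidermis genes (0.882). Hist1h2al was lowest in p53 het 3 (0.908), S100a9 highest in p53 het 1 (0.830) and Pmepa1 highest in p53 het 2 (0.845). Among R172H tumours, R172H 6 was highest for p53 target genes (0.637), immediate early genes (0.663), Egr1 (0.729) and Mrps34 (0.754), and lowest for Hist1h2al (0.879). R172H 2 was lowest for Xist (0.669) and the only R172H library with reads of Krtdap (1). R172H 4 was highest for Ndufa4 (0.658) and R172H 5 for Alas2 (0.821). Among R270H tumours, R270H 3 was highest for epithelial-mesenchymal transition genes (0.822), Rn7s2 (0.761), Rny3 (0.766), Heyl (0.745), Egr1 (0.75) and Egr3 (0.871), and lowest for adipocyte genes (0.717) and Mx2 (0.713). R270H 4 was highest for Muc2 (0.863), Flt1 (0.892) and Krt10 (0.770), and lowest for osteoclast genes (0.751), BC002163 (0.752), B2m (0.787) and Ocstamp (0.782). R270H 5 was highest for Cxcr2 (0.811), Mmp8 (0.718) and Car2 (0.751), and lowest for mevalonate genes (0.847) and Psma4 (0.776). R270H 2 was lowest for Rpl34 (0.796).

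The first pattern is the 1088 genes that differ between R270H and R172H tumours, whose titles differ in kind. On the log2 scale, p53 het 3 and 4 exceeded 1 and 2 in the R270H direction by a median of 0.395 over these genes. The other ways to pair the 4 libraries gave 0.162 and -0.01. A batch marked by the titles would give this. The bootstrap interval, 0.363 to 0.430, resampled genes, which are not independent. It does not measure the spread between libraries, of which each side holds 2. The second principal component had already placed p53 het 3 and 4 (51.1 and 6.58) above p53 het 1 and 2 (-3.21 and -19.7), toward R270H, so the test largely restates what was seen and adds little support. With the code as a covariate the median signed log2 fold fell from 1.08 to 0.57, its median standard error rose from 0.251 to 0.442 and 1 call was left, so the calls ended through both. Genes higher in R270H had a median GC content of 45.0% and those lower of 54.4%, so GC content may have a part in the pattern. As the whole cause it is argued against, since 75.9% as many genes passed with each library's trend removed (826, of which 718 were among the 1088). Chance is argued against in that 1 of 100 splits gave as many genes, the real one, with at most 1 gene in the others; the splits do not bear on a bias that follows the groups, such as one of GC content. Only p53 het holds both kinds of title, and a part due to genotype stays open beside a batch. The R270H titles share a code that p53 het 3 and 4 lack, so a batch under that code cannot be tested. The 4 p53 het tumours can also differ in traits that the labels do not give, such as the site.

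The second pattern is the 12 genes set apart in all R245W tumours from each of the other 3 groups, 6 higher and 6 lower. Of these, 3 (Ndufs5, Rhbdl2 and Gm12904 on chromosome 4) lie within 5 Mb of another, as in 428 of 10000 random sets, and in both libraries of the line 11 of the 12 lay on the R245W side, which is consistent with strain variants carried along with the R245W mice; with a window set after the result this is a hypothesis. Gm18862, higher in the R245W tumours, had no read in the line and so lay on the other side. Foxo1 and Rpl34, called in R245W against p53 het but not among the 12, also lay away from the R245W tumours in the line. Foxo1 had 11.9 and 9.80 CPM there, against a mean of 108 CPM in these tumours. Rpl34 had 292 and 321 CPM, against 21.6 CPM. For Zcchc17 the line is not reported here. Gm12904, lower in them, had 0.0156 and 0.0136 CPM in the line, under the floors of 0.0468 and 0.0409 CPM, and lends little support. When Trp53 RNA was lowered in the line, the genes moved by a median of -0.134 log2 units toward the other tumours, that is, slightly away, and with 1 library per arm this does not exclude that the mutant protein keeps them changed. Reads shared between a parent gene and its copies also stay open. The test gave 0.529, the log2 fold of summed reads over that of the gene, but from Rpl34, which is not one of the 12, so it decides nothing for them. Among the 12, Rpl15-ps2 and Rpl3-ps1 had 0.104 and 0.0187, where a change in the gene alone gives 0.107 and 0.0722, too near 0 to tell these apart.

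The third pattern is the 10 small RNA genes lower in R172H than in p53 het tumours. Their median log2 fold was -5.31 against all 4 p53 het libraries (median standard error 0.917) and -0.70 against p53 het 1 and 2 (0.50), where none passed in edgeR. Summed over these genes, p53 het 3 and 4 had 3729 and 897 CPM and p53 het 1 and 2 had 56.6 and 81.2 CPM. R172H tumours had at most 58.0 CPM. A batch marked by the titles would give this, though no label gives one. The test was set after levels of some small RNAs were seen, so it largely restates them. The share of all small non-coding RNA in the counts did not follow the titles. It was 5.92% and 3.14% in p53 het 3 and 4, and 5.97% and 5.04% in p53 het 1 and 2. A general difference in how small RNA was kept is thus not shown. No biological explanation was tested.

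Redrawn groups bear on the counts of genes. In R172H against p53 het 2 of 100 splits gave at least the real 16 genes, and the other of them, with p53 het 1 in exchange for R172H 6, gave 228, which points to a structure of the samples beyond genotype. In R245W against p53 het 5 of 35 splits gave as many as the real 15, so chance is not excluded for the count. The highest, 207, put p53 het 3, p53 het 4 and R245W 2 together, and the next, 90, p53 het 2, p53 het 4 and R245W 2. With R245W 1 or R245W 3 beside p53 het 3 and 4 the splits gave 0 genes, so the titles alone do not account for the high counts. Common to both high splits were p53 het 4 and R245W 2, the highest libraries on PC1 (80.1 and 84.9). Within serial-numbered titles 9 genes passed. For R270H against p53 het, with 0 genes, all 100 splits gave as many, as any split must, so they decide nothing there. The highest other gave 2. Chance is excluded at 1 in 20 for R245W against R172H (32 genes; 1 of 84 splits, highest other 6), R245W against R270H (255 genes; 1 of 56, highest other 6) and any genotype (590 genes; 1 of 100, highest other 153), though in the contrast with R270H the titles follow the groups, and for any genotype they do in part.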

How the results depend on the processing

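The tests with the title code, only p53 het 3 and 4, GC content and protein-coding genes were chosen after the data were seen. Counts are given in the order R172H, R245W and R270H against p53 het, R245W against R172H, R245W against R270H, R270H against R172H, and any genotype. DESeq2 called 307, 371, 329, 352, 1201, 2243 and 2513 genes where edgeR called 16, 15, 0, 32, 255, 1088 and 590, and shared 69, 26 and 20 genes between contrasts. It called Trp53 in R172H (log2 fold 1.17, adjusted p = 0.00661) and R245W (1.57, 0.00101), and removal of the GC trend called it in R245W (1.62, 0.0352). Without a low-count filter the counts that moved by over 1.5 times were 33, 2, 109 and 633 (R172H and R270H against p53 het, R245W against R270H, R270H against R172H). With limma voom these were 0, 1, 119, 1047, 2294 and 330 (all but R245W against p53 het). A fit of only the groups compared gave 0, 4 and 1638 (R172H and R245W against p53 het, R270H against R172H). Without p53 het 3 and 4 there were 4, 9, 94 and 503 (each mutant against p53 het, R245W against R270H). A muscle score as covariate gave 0 and 345 (R172H against p53 het, any genotype), Xist 0, and 1 surrogate variable 0, 2 and 16 (R172H and R270H against p53 het, R245W against R172H). The title code as covariate gave 3, 8, 4, 8, 1 and 19 (all but R245W against R172H), and p53 het 3 and 4 alone 4. Protein-coding genes alone gave 0, 3, 1 and 241 (R172H and R245W against p53 het, R245W against R172H, any genotype). The size factors of DESeq2 in edgeR moved no count by over 1.5 times.

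Leaving out 1 library gave 0 to 166, 5 to 30, 0 to 21, 14 to 39, 48 to 411, 469 to 1323 and 185 to 937 genes. The Trp53 log2 folds then ran from 1.02 to 1.41, 1.42 to 1.81, 0.57 to 0.98, 0.26 to 0.50, 0.69 to 1.01 and -0.60 to -0.33. Directions turned with the title code for Rn7s6 (0.72 in R245W against R270H, -1.03 in R270H against R172H) and Rn7s2 (-0.93). List tests that turned were oxidative phosphorylation in R172H (adjusted p = 0.916 without p53 het 3 and 4, 0.832 with the code) and in R245W against p53 het (0.942 and 0.855), posterior Hox genes in R172H against p53 het (0.557 and 0.532), the proteasome in R245W against R270H (0.529) and R270H against R172H (0.832), and, without R245W 2, DNA replication in R245W against R172H (0.904; from 2.14e-05 to 0.904 over the libraries left out). Of 44 list calls 0 passed with an estimated correlation or fry, 43 were kept without a filter, 44 with the other size factors, 42 with the muscle score, 27 without p53 het 3 and 4 and 24 with the code. In the line Trp53 had -1.49 with CPM plus 5. Apart from the title code, GC content and redrawn groups, the cause was not tested. At this depth genes under 0.103 to 0.149 CPM cannot be told from 0.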

Other observations

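Perp, a cell adhesion gene that p53 activates, was higher in R270H than in R172H tumours (12.5 against 0.864 CPM; log2 fold 3.85 ± 0.98, edgeR adjusted p = 0.0307), most of it from R270H 4, without which the log2 fold was 1.96 and the adjusted p 0.159. In the same comparison Dnajc3 (0.84 ± 0.20, 0.0251) and Pdia6 (0.86 ± 0.24, 0.0467), both of protein folding, and the chemokine Cxcl5 (3.88 ± 1.05, 0.0444) were higher, and Tap2 (-0.99 ± 0.25, 0.0307), the macrophage marker Cd68 (-1.45 ± 0.40, 0.0444) and Kmt2d (-0.73 ± 0.19, 0.0351) lower. All 7 members lost their calls with the title code as a covariate. Without R270H 4 Pdia6 (0.119), Cxcl5 (0.260, log2 fold 1.64), Tap2 (0.0725) and Cd68 (0.0904) did not pass, without R270H 3 Dnajc3 (0.0660), and without R270H 1 Kmt2d (0.0885). Of the 18 leave-one-out fits Pdia6 and Cd68 lost their calls in 11 each, Cxcl5 in 10, Kmt2d in 9, Perp in 8, Tap2 in 6 and Dnajc3 in 5.

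Cell types were uneven between tumours of a genotype. The mean log2 CPM of skeletal muscle genes was highest in p53 het 4 (7.52), R270H 2 (6.56) and R172H 6 (6.49), and that of osteoclast genes was 2.75 in p53 het 4, 3.14 in R270H 4 and 4.35 in R245W 2.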
